A study of Homo sapiens with 6 samples.

How the data were processed

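RNA was measured on 6 arrays of AGS, a human gastric adenocarcinoma cell line. Of these arrays, 3 were of cells given a lentivirus carrying a short hairpin RNA against NCAPD3, with the knockdown described as stable, and 3 were of cells given the control vector. Per the labels' protocols, the cells were grown in serum-containing medium, RNA was taken with Trizol and checked on a NanoDrop, and biotin-labelled RNA was hybridised to Affymetrix GeneChip PrimeView arrays, which carry several short probes per transcript combined into probe sets. The number of hairpin sequences and the time after transduction are not given in the sources used here. The labels do not say whether the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

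The deposited values are log2 intensities, 1 column per array. Per the submitters' processing notes the authors used RMA, which corrects for background, makes the distributions of the arrays alike and summarises each probe set. Its version is not stated. The log2 scale was read from the values, which ran from 2.52 to 13.98, with array medians from 6.12 to 6.19. RMA rescaling removes a shift shared by most genes, so every change is relative to the other genes on the arrays, and it compresses changes of dim genes. No scanner files, scan dates or detection calls were used here, so background could not be corrected again and no array batch could be tested. The number of arrays limits the precision.

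The table held 39224 probe sets, of which 72 were control probe sets. The platform annotation gave 1 gene symbol to 35875 probe sets, several to 1433 and none to 1850 that were not controls. Probe sets of the last 2 kinds were not used for genes. Some control probe sets carry a gene symbol and so enter both counts, and any with 1 symbol were not removed from the tests of genes. The other control probe sets were left out. By Entrez number 35857 of the single-gene probe sets matched the RefSeq gene table and 18 did not, and no symbol had to be updated (0 changed). The probe set with the highest mean over the 6 arrays stood for each gene, which gave 15309 genes, 9263 of them with several probe sets. Genomic positions are not printed, because the build of that table is not named.

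Knockdown was compared with control in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, with no trend and no robust prior) and Benjamini-Hochberg adjustment over all genes, and genes with an adjusted p under 0.05 are called changed. A second count required at least a 2-fold change, an absolute log2 fold change of 1. Log2 fold changes are knockdown minus control and are given ± the standard error of the model, with n = 3 arrays per group throughout. Adjusted p-values of genes are from limma, and adjusted p-values of gene lists are from limma's camera with a preset correlation of 0.01, adjusted over 33 lists. Camera was run again with the correlation between members estimated in each list. The lists cover condensins and cohesin, the cell cycle, DNA repair, stress responses, metabolism, ribosomes, signalling pathways, epithelial and mesenchymal genes, stomach and intestinal markers, markers of other cell types, and genes sensitive to handling.

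The 33 lists, the comparison of genes and lists and the rule for naming genes were fixed before the data were examined, as were the alternatives other than the scaling to the hybridization controls. The tests of explanations in the closing section, and its list of splicing and cleavage factors, were set after the data had been opened. The rule named NCAPD3 and the other condensin subunits, then the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, leaving out open reading frame and LOC symbols. From each list it named up to 4 called members with the largest change. Other genes are said to have been chosen after their values were seen. The NCAPD3 values were also compared with an exact two-sided permutation test. The fit of genes was tested on simulated data for this comparison, with 15309 genes drawn independently and 50 genes changed at each size. Normalization and the choice of probe sets were not part of that test. The fit recovered 8 of 50 genes changed 1.2-fold, 41 of 50 changed 1.5-fold, and 50 of 50 at both 2-fold and 4-fold, with 17 false calls. Far fewer genes were changed there than were called in the data, so these shares need not hold for the data.

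The alternatives were a replicate block, leaving out each array, quantile and cyclic loess normalization, a shift of each array to 1 median, a floor at the 20th percentile, leaving out genes below the 40th percentile of mean intensity, a trended robust prior, array weights, the mean of a gene's probe sets, every probe set, limma's treat against 1.2-fold, camera with an estimated correlation, and fry. Scaling to the hybridization controls, which are bacterial and phage transcripts added to each array, was chosen after seeing the data. It takes the same value off every gene of an array, so fold changes relative to the other genes stay as they were. A list call kept or gained under it is therefore no separate support. Both groups carry replicate numbers 1 to 3 in the labels. Over genes, deviations from the group means correlated between same-numbered arrays at r = 0.138, 0.335 and 0.121, and between other pairs at -0.214 to 0.121. All 3 same-numbered pairs exceeded 0.1, so the numbers were taken to pair the arrays in the replicate block. Control replicate 3 with knockdown replicate 1 also reached 0.121, so the correlations do not clearly separate same-numbered from other pairs. The pairing by number comes from the data and is uncertain, since the labels do not say what a number marks.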

Results

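Gene expression was measured on PrimeView arrays in AGS gastric cancer cells with a stable short hairpin knockdown of NCAPD3 and in cells with the control vector, 3 arrays per group. NCAPD3 is a subunit of condensin II, a complex that compacts chromosomes. The comparison asks which transcripts differ between the knockdown and the control cells. All 6 arrays carried 39224 probe sets, and 15309 genes were tested. Arrays within a group correlated at r = 0.9966 to 0.9980 over probe sets and differed by 0.130 to 0.178 log2 units (root mean square), against r = 0.969 to 0.972 and 0.484 to 0.517 between groups. The first principal component held 88.3% of the variance and separated the groups, and the second held 4.95%. Probe sets are not independent replicates, and no pair of arrays held identical values.

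NCAPD3 was lower on every knockdown array. Its 1 probe set (11720550_a_at) read 8.17, 8.12 and 8.22 on the control arrays and 7.50, 7.56 and 7.43 on the knockdown arrays. The group means were 8.17 ± 0.051 and 7.49 ± 0.065 (SD), a log2 fold change of -0.68 ± 0.052, which left 62.6% of the control level (95% confidence interval 57.5% to 68.2%). The limma adjusted p was 4.33e-05, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 arrays allow. NCAPD3 was not among the largest falls, as 1163 genes fell by more.

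The other condensin subunits moved little. In condensin II, NCAPH2 fell (-0.26 ± 0.046, adjusted p = 0.00249), whereas NCAPG2 stood at -0.07 ± 0.038 (adjusted p = 0.178). With NCAPD3, 0 of the 3 measured members of the condensin II list rose and 2 fell, with the same counts adjusted over the list alone, a median of -0.26 (0.032 with the mean of probe sets) and a list adjusted p of 0.132. Of the 5 members of condensin I and the shared subunits, 0 rose and 1 fell, again with the same counts adjusted over the list alone (adjusted p = 0.789). That member was NCAPG (-0.20 ± 0.049, adjusted p = 0.0131). NCAPD2 (0.03 ± 0.044), NCAPH (0.04 ± 0.045), SMC2 (0.05 ± 0.057) and SMC4 (-0.14 ± 0.054) did not pass, although SMC4 passed after quantile normalization (adjusted p = 0.031), without dim genes (0.0311), with a trended robust prior (0.00244) and with array weights (0.0471). The condensin I median was 0.03, its mean was -0.04 and its test pointed down. The probe sets of SMC4 and of NCAPH2 were called in both directions. NCAPD2, NCAPH, SMC2, SMC4 and NCAPG2 were called lower when the arrays were scaled to the hybridization controls, the NCAPG call was lost without knockdown replicate 3 (adjusted p = 0.0543). With the mean of all probe sets NCAPG stood at -0.078 (adjusted p = 0.268) and NCAPH2 at 0.032 (0.513), neither called, and NCAPG2 was called higher (0.21, adjusted p = 0.00851).

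**Figure D1:**
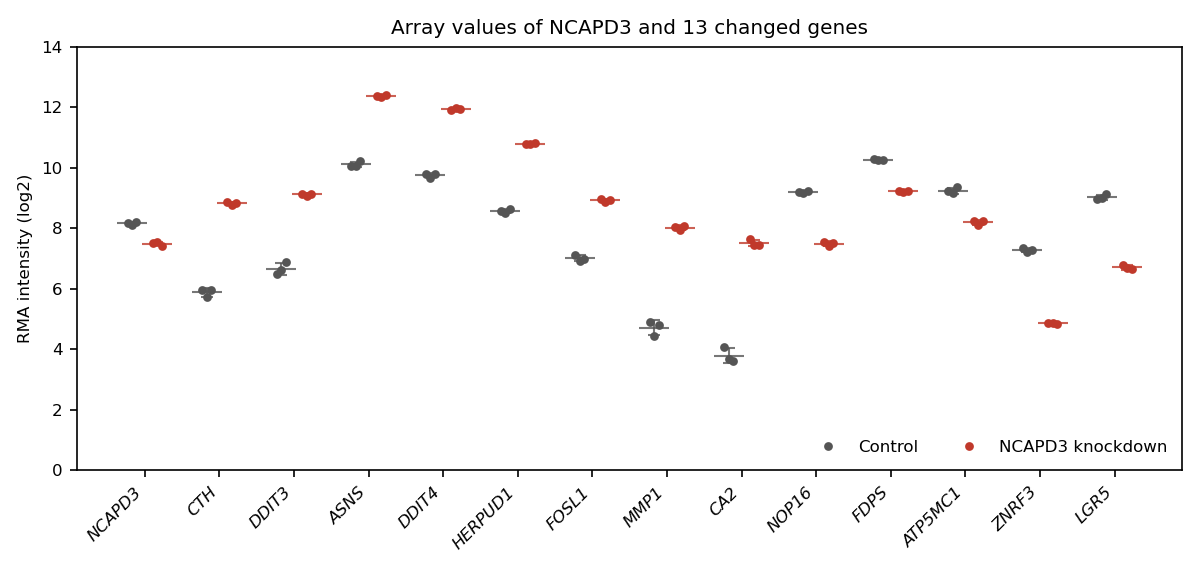
RMA log2 intensity of NCAPD3 and 13 changed genes on each array, with control in grey and knockdown in red; points are arrays, dashes are group means and bars are SD (n = 3). The groups do not overlap for any plotted gene, and NCAPD3 shows the smallest difference, from a mean of 8.17 to 7.49.

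Changes were spread over the transcriptome and most were small. Of 15309 genes, 8167 (53.3%) were called, 3855 higher and 4312 lower in the knockdown. At least 2-fold changes were found in 746 genes (4.87%), 325 higher and 421 lower. The median absolute log2 fold change of called genes was 0.41, and 5691 of them (69.7%) changed under 1.5-fold. The split between higher and lower depended on the scaling. Called genes were 47.2% higher as deposited and 20.3% higher (1802 against 7086) when scaled to the hybridization controls, which were 0.212 higher on the knockdown arrays and moved the median of all genes from 0.045 to -0.17. Of at least 2-fold calls, 189 were then higher and 804 lower, or 19.0% higher against 43.6%.

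Among the largest rises was that of CA2, a carbonic anhydrase, from a mean of 3.78 to 7.51 (3.73 ± 0.12, adjusted p = 2.21e-06). SPRR2D, a cornified envelope protein (3.53 ± 0.12), and MMP1, a collagenase (3.32 ± 0.12), were close to it. The same 12 held TCP11L2 (3.16 ± 0.072), CTH, which makes cysteine from cystathionine (2.95 ± 0.074), and the myosin heavy chain MYH4 (2.94 ± 0.057). The epithelial transcription factor GRHL2 (2.65 ± 0.10), the microsomal chaperone HSPA13 (2.60 ± 0.063) and XKR9 (2.53 ± 0.095) were also among them. The stress-induced transcription factor DDIT3 (2.46 ± 0.093), LYPD3 (2.40 ± 0.098) and the hypoxia-inducible gene NDRG1 (2.39 ± 0.044) completed the 12. Control means of CA2, SPRR2D, MMP1, TCP11L2, GRHL2 and XKR9 lay below 4.77, the upper bound of the dimmest quartile of genes, where a fold change is less exact. With values floored at the 20th percentile the order changed, with SPRR2D at 3.34, MMP1 at 3.32, CA2 at 3.15, TCP11L2 at 2.35 and XKR9 at 1.83. The probe sets used for SPRR2D, MYH4, HSPA13, DDIT3 and NDRG1 are of types (_x_at or _s_at) that can also match related transcripts. Those of GRHL2 disagreed, with 2 of 5 higher and 2 lower. With the mean of their probe sets GRHL2 stood at 0.67 and HSPA13 at 1.35.

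The largest fall in log2 value was that of KRCC1, from 6.80 to 3.62 (-3.18 ± 0.15). ZCCHC14 (-2.61 ± 0.082), OSGEPL1 (-2.45 ± 0.089) and the protocadherin PCDH7 (-2.44 ± 0.082) came next. Both ZNRF3, a ubiquitin ligase that removes Wnt receptors (-2.42 ± 0.047), and LGR5, an R-spondin receptor and stem cell marker (-2.33 ± 0.062), fell about as far. PANK1, which starts coenzyme A synthesis, fell by 2.39 ± 0.070, and the nuclear receptor coactivator NCOA6 fell by 2.38 ± 0.052. The other 4 were REG1A (-2.32 ± 0.090), the phosphatase 1 subunit PPP1R10 (-2.29 ± 0.078), C1RL (-2.27 ± 0.084) and the dynein assembly factor DNAAF5 (-2.24 ± 0.051). Knockdown means of KRCC1, OSGEPL1 (4.10), PCDH7 (4.73) and C1RL (4.58) lay below 4.77, in the range of the dimmest quartile, so their folds and order are less exact. With values floored at the 20th percentile, KRCC1 stood at -2.40 and OSGEPL1 at -2.15, and with the mean of their probe sets ZCCHC14 stood at -1.34 and PCDH7 at -1.22. The probe sets used for OSGEPL1, PANK1 and DNAAF5 are of a type (_s_at) that can also match related transcripts.

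**Figure D2:**
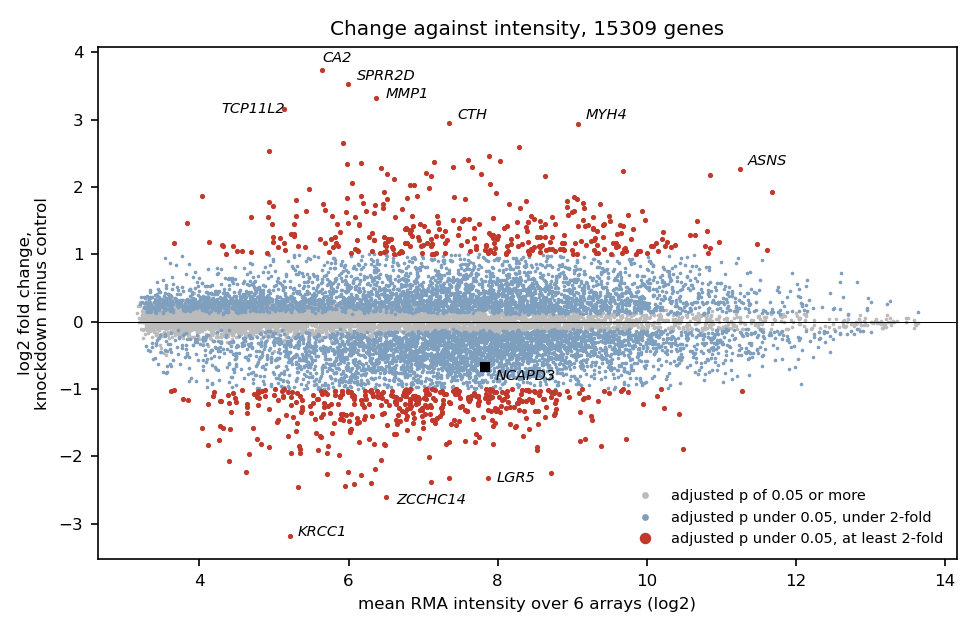
Log2 fold change (knockdown minus control) against mean log2 intensity over 6 arrays for 15309 genes; grey points did not pass, blue points passed with under 2-fold change, red points passed with at least 2-fold change, and the black square is NCAPD3. Of the 746 red points, 325 lie above 0 and 421 below as deposited, against 189 and 804 when scaled to the hybridization controls.

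Genes of the integrated stress response, the program driven by the transcription factor ATF4, rose together. Of 27 measured members 24 rose, 0 fell and 3 did not pass, with the same counts adjusted over the list alone, and 16 rose at least 2-fold. CTH and DDIT3 led, followed by asparagine synthetase ASNS (2.26 ± 0.056, 4.79-fold) and the mTORC1 inhibitor DDIT4 (2.18 ± 0.051, 4.53-fold). The median was 1.07 and the list adjusted p was 3.69e-12, with an adjusted p = 0.264 with an estimated correlation. ATF4 itself, chosen after its values were seen, rose by 0.37 ± 0.040. The members that did not pass, named for the same reason, were ALDH1L2 (0.22 ± 0.11), PHGDH (0.15 ± 0.069) and SLC7A1 (0.12 ± 0.056).

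Endoplasmic reticulum chaperone genes also rose, with 16 of 22 higher, 2 lower and 4 not passing, the same counts adjusted over the list alone, and a median of 0.32 (adjusted p = 0.000283; adjusted p = 0.264 with an estimated correlation). HERPUD1, which acts in the degradation of misfolded proteins, rose 4.72-fold (2.24 ± 0.047). The co-chaperone DNAJB9 (1.26 ± 0.066), MANF (0.74 ± 0.037) and SEL1L (0.73 ± 0.044) followed, as did the main chaperone HSPA5 (0.73 ± 0.040), chosen after its values were seen. The members that fell, likewise named afterwards, were DERL1 (-0.12 ± 0.042) and SEC61B (-0.22 ± 0.039), of which DERL1 was not called without control replicate 1 or 3 or any knockdown replicate (adjusted p 0.083 to 0.127). Scaled to the hybridization controls, 11 chaperone genes rose and 4 fell (median 0.11). The list was called there too (adjusted p = 0.000257), which adds no separate support because all genes shifted alike. Autophagy and lysosome genes gave 12 of 22 higher and 7 lower (13 and 7 adjusted over the list alone), and the list was not called (median 0.23, adjusted p = 0.123). It was called higher with a trended robust prior (adjusted p = 0.029) and when scaled to the hybridization controls (0.0173), where 9 rose and 8 fell. That scaling left its fold changes relative to the other genes unchanged, so the gained call is no larger relative rise. The autophagy kinase ULK1 (1.85 ± 0.048), MAP1LC3B (1.51 ± 0.063), NPC1 (1.27 ± 0.051) and GABARAPL1 (1.10 ± 0.059) rose.

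MYC targets and ribosome biogenesis genes fell together. Of 29 MYC targets and ribosome biogenesis genes 26 fell, 1 rose and 2 did not pass (median -0.75, adjusted p = 1.27e-09; adjusted p = 0.264 with an estimated correlation). The nucleolar proteins NOP16 (-1.69 ± 0.054, 3.24-fold), RRS1 (-1.25 ± 0.046) and NOLC1 (-1.22 ± 0.048) and the large ribosomal subunit assembly factor WDR12 (-1.17 ± 0.053) moved most. MYC fell by 0.53 ± 0.041 and the one riser was ornithine decarboxylase ODC1 (0.83 ± 0.047), both named after their values were seen. Among cytosolic ribosomal proteins, 0 of 28 rose and 6 fell (4 adjusted over the list alone), and the list was not called (median -0.06, adjusted p = 0.132). It was called lower with a trended robust prior (adjusted p = 0.0363) and when scaled to the hybridization controls (0.0015), where 28 of 28 fell. That scaling lowered all genes alike, so it did not widen the fall relative to the other genes. RPL13 (-0.32 ± 0.047), RPL4 (-0.21 ± 0.043), RPL3 (-0.19 ± 0.038) and RPL14 (-0.16 ± 0.039; -0.11, adjusted p = 0.0584, with the mean of its probe sets) fell most.

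Of 28 oxidative phosphorylation genes 0 rose, 23 fell and 5 did not pass, against 0 and 24 adjusted over the list alone (median -0.27, adjusted p = 3.04e-07; adjusted p = 0.264 with an estimated correlation). The ATP synthase subunit ATP5MC1 (-1.05 ± 0.068), the complex I subunits NDUFA8 (-0.84 ± 0.040) and NDUFB10 (-0.81 ± 0.046) and the cytochrome oxidase subunit COX5A (-0.67 ± 0.041) fell most, although 1 of the 2 probe sets of NDUFA8 was higher and their mean stood at -0.23. Of 19 cholesterol synthesis genes 14 fell, 2 rose and 3 did not pass (median -0.54, adjusted p = 0.000283; adjusted p = 0.264 with an estimated correlation). The enzymes FDPS (-1.05 ± 0.040), ACAT2 (-1.04 ± 0.039), DHCR7 (-1.03 ± 0.049) and LSS (-0.91 ± 0.060) led the fall. The risers, named after their values were seen, were the pathway's transcription factor SREBF2 (0.18 ± 0.056) and STARD4 (0.20 ± 0.063), and both turned negative when scaled to the hybridization controls, as SREBF2 did with the mean of its probe sets (-0.14). The SREBF2 call was lost when any single array other than control replicate 2 was left out (adjusted p 0.0744 to 0.105). The STARD4 call was lost without control replicate 1 or 2 or knockdown replicate 1 (0.0629 to 0.102) and with a replicate block (0.0591). Glycolysis and hypoxia genes went both ways, with 11 of 27 higher and 11 lower (11 and 12 adjusted over the list alone; median 0.02, adjusted p = 0.895; 9 and 15 when scaled to the hybridization controls). NDRG1, BNIP3L (1.69 ± 0.052), PDK1, which restrains pyruvate entry into mitochondria (1.01 ± 0.063), and hexokinase HK2 (0.95 ± 0.057) rose. With the mean of its probe sets PDK1 stood at 0.51. For the MYC and cholesterol lists the counts were the same adjusted over the list alone.

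**Figure D3:**
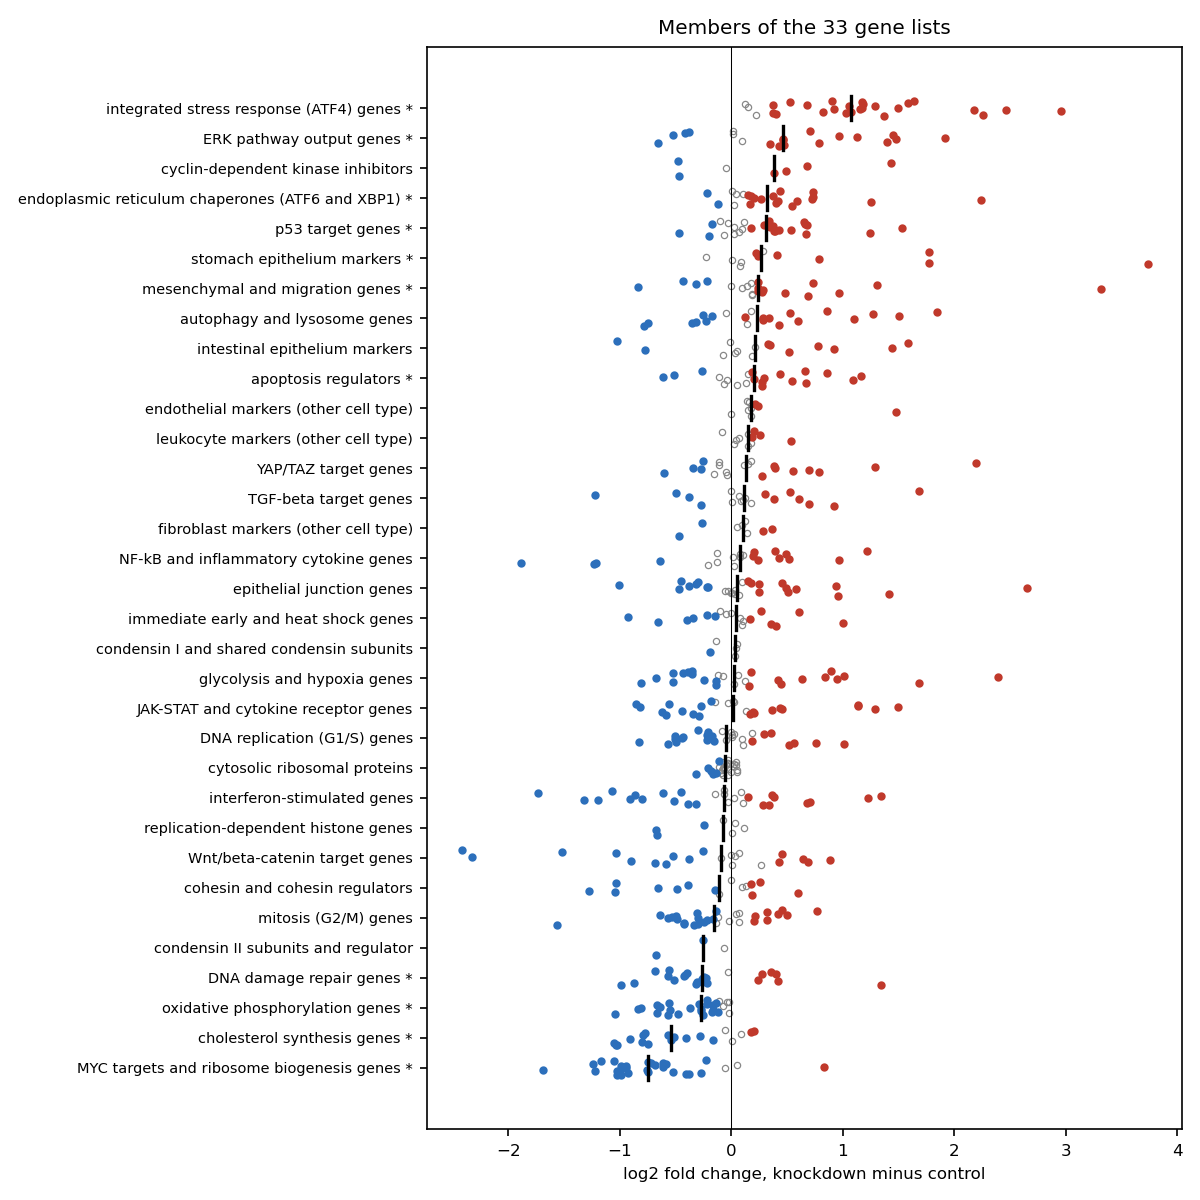
Log2 fold change (knockdown minus control) of each measured member of the 33 gene lists, ordered by median; filled points passed (red higher, blue lower), open points did not, black bars are medians and stars mark lists with a camera adjusted p under 0.05. The ATF4 list has the highest median (1.07) and the MYC list the lowest (-0.75); 11 lists carry a star, and 0 pass with an estimated correlation.

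No cell cycle list was called. Of 30 mitosis genes 8 rose and 16 fell (median -0.15, adjusted p = 0.159), among them the spindle gene ASPM (-1.57 ± 0.072), the checkpoint kinase TTK (0.76 ± 0.048), the proliferation marker MKI67 (-0.64 ± 0.052; -1.61 with the mean of its probe sets) and CENPF (-0.57 ± 0.044). Of 29 DNA replication genes 7 rose and 13 fell (median -0.045, adjusted p = 0.382). CDC6 (1.01 ± 0.042) and E2F1 (0.76 ± 0.056) rose and GINS1 (-0.83 ± 0.039) and CDC45 (-0.57 ± 0.055) fell. Cohesin and its regulators gave 4 of 15 higher and 7 lower (5 and 7 adjusted over the list alone; median -0.11, adjusted p = 0.31). The cohesin loader MAU2 (-1.27 ± 0.059), the acetyltransferase ESCO2 (-1.05 ± 0.076), STAG1 (-1.04 ± 0.062) and PDS5B (-0.66 ± 0.064; -0.16, adjusted p = 0.0836, with the mean of its probe sets) fell. The risers, named after their values were seen, were ESCO1 (0.59 ± 0.052), STAG2 (0.25 ± 0.051), CDCA5 (0.19 ± 0.049) and SMC3 (0.17 ± 0.042), and CDCA5 and SMC3 turned negative and STAG2 did not pass when scaled to the hybridization controls. CDCA5 was not called without knockdown replicate 1 (adjusted p = 0.0533) or 3 (0.0576), nor SMC3 without knockdown replicate 3 (0.0508). Only 7 of the 20 listed replication-dependent histone genes were measured, so the list says little about histone expression as a whole. Of these 7, 0 rose and 3 fell (0 and 2 adjusted over the list alone), with a median of -0.08 and a list adjusted p of 0.269. The fallers were H2BC12 (-0.68 ± 0.053), H1-2 (-0.66 ± 0.047) and H2BC5 (-0.25 ± 0.086). H2BC5 was not called without control replicate 1 or 3 or knockdown replicate 1 or 2 (adjusted p 0.116 to 0.129). Of 7 cyclin-dependent kinase inhibitors 4 rose and 2 fell (median 0.38, adjusted p = 0.382). Among them CDKN2D (1.43 ± 0.055), CDKN2B (0.68 ± 0.063) and CDKN1C (0.49 ± 0.073) were higher. The fallers were CDKN3 (-0.48 ± 0.052) and CDKN1A (-0.47 ± 0.039), the latter named after its values were seen. Scaled to the hybridization controls, 5 mitosis genes rose and 22 fell (median -0.37), 5 replication genes rose and 19 fell (median -0.26) and 1 cohesin gene rose and 9 fell, without any of these lists being called relative to the other genes. The replication median was 0.0007 under cyclic loess. For the mitosis, replication and inhibitor lists the counts were the same adjusted over the list alone.

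DNA repair genes were mostly lower, while p53 targets and apoptosis regulators were mostly higher as deposited. Scaled to the hybridization controls, 11 p53 targets rose and 8 fell (median 0.10) and 7 apoptosis regulators rose and 7 fell (median -0.01). Both lists were called higher there too (adjusted p = 0.00145 and 0.0149), which adds no separate support because all genes shifted alike. Of 24 repair genes 17 fell, 6 rose and 1 did not pass (median -0.27, adjusted p = 0.0449; adjusted p = 0.446 with an estimated correlation). The checkpoint kinase ATR (-0.99 ± 0.095), BRCA1 (-0.87 ± 0.070) and XRCC5 (-0.69 ± 0.061) fell, and ATM rose (1.34 ± 0.088) on the probe set used, while 2 of its 4 probe sets were lower and their mean was not called (0.06, adjusted p = 0.347). Of 26 p53 targets 15 rose, 3 fell and 8 did not pass (median 0.31, adjusted p = 0.005; adjusted p = 0.403 with an estimated correlation). PLK3 (1.53 ± 0.059), CYFIP2 (1.24 ± 0.072; 0.24 with the mean of its probe sets), SESN2 (0.68 ± 0.044), which the ATF4 list also holds, and the proapoptotic BBC3 (0.66 ± 0.041) rose. The fallers, named after their values were seen, were the cell cycle inhibitor CDKN1A (-0.47 ± 0.039), AEN (-0.21 ± 0.043) and TIGAR (-0.18 ± 0.059), of which TIGAR was not called with a replicate block (adjusted p = 0.0597) or without replicate 1 or 3 of either group (0.0602 to 0.118) but stood at -1.25 with the mean of its probe sets. Of 21 apoptosis regulators 12 rose, 3 fell and 6 did not pass (median 0.20, adjusted p = 0.0449; adjusted p = 0.264 with an estimated correlation and 0.0684 with a replicate block). The caspase inhibitor CFLAR (1.17 ± 0.045; 0.37 with the mean of its probe sets) and the proapoptotic BIK (1.09 ± 0.040), PMAIP1 (0.86 ± 0.039) and BBC3 rose. CASP8 (-0.61 ± 0.048, with 2 of 8 probe sets higher), DIABLO (-0.52 ± 0.041) and the caspase inhibitor XIAP (-0.27 ± 0.057), named after their values were seen, fell. With the mean of their probe sets CASP8 stood at -0.17 and XIAP at -0.14. The p53 and apoptosis lists share BAX, BBC3 and TNFRSF10B. Counts for all 3 lists were the same adjusted over the list alone. The repair call was lost without control replicate 3 (adjusted p = 0.0729) or knockdown replicate 3 (0.0502) and under several rescalings, the apoptosis call without control replicate 2 (0.0637), control replicate 3 (0.0554) or knockdown replicate 3 (0.0504), and the p53 call with the mean of probe sets (0.0851).

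Output genes of the ERK pathway rose in 13 of 20 cases, fell in 4 and did not pass in 3 (median 0.46, adjusted p = 0.005; adjusted p = 0.403 with an estimated correlation). The AP-1 component FOSL1 (1.91 ± 0.062, 3.76-fold; 1.27 with the mean of its probe sets), ETV5 (1.47 ± 0.074), PHLDA1 (1.45 ± 0.044) and EPHA4 (1.40 ± 0.037; 0.81 with the mean of its probe sets) rose most. MYC, EGR1 (-0.66 ± 0.039), SPRED2 (-0.42 ± 0.057) and SPRY1 (-0.38 ± 0.076) fell, the last 2 being feedback inhibitors named after their values were seen. Wnt target genes were split, with 5 of 21 higher and 10 lower (6 and 10 adjusted over the list alone; median -0.09, adjusted p = 0.133). Besides ZNRF3 and LGR5, SP5 (-1.52 ± 0.042) and the ZNRF3 paralog RNF43 (-1.03 ± 0.053) fell. AXIN2 fell on the probe set used (-0.59 ± 0.048) while 2 of its 3 probe sets were higher and their mean stood at 0.033 (adjusted p = 0.567). EPHB3 (0.89 ± 0.091), CD44 (0.68 ± 0.048), FGF18 (0.64 ± 0.16), NOTUM (0.46 ± 0.059) and CCND1 (0.43 ± 0.043) rose. AXIN2 and these 5 were named after their values were seen. FGF18 stood at 0.36 with values floored at the 20th percentile and was not called when scaled to the hybridization controls (0.43, adjusted p = 0.0694), where 4 Wnt targets rose and 12 fell. For the ERK list the counts were the same adjusted over the list alone.

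Lists of 5 further signalling pathways were not called. YAP/TAZ targets gave 8 of 20 higher and 4 lower (median 0.13, adjusted p = 0.211), with PTPN14 (2.19 ± 0.060), tissue factor F3 (1.29 ± 0.045), ASAP1 (0.79 ± 0.052) and CCN1 (0.69 ± 0.070) higher, and ANKRD1 (-0.61 ± 0.10), CCN2 (-0.27 ± 0.047), DLC1 (-0.35 ± 0.078) and WWC1 (-0.26 ± 0.054) lower. TGF-beta targets gave 7 of 18 higher and 4 lower (median 0.11, adjusted p = 0.211), with THBS1 (1.68 ± 0.056), BHLHE40 (0.92 ± 0.045) and COL4A1 (0.69 ± 0.051) higher and SMAD6 (-1.23 ± 0.095; -0.60 with the mean of its probe sets), TAGLN (-0.50 ± 0.055), SKI (-0.38 ± 0.044) and CCN2 lower. The fallers of these lists other than SMAD6 were named after their values were seen. ANKRD1 was dim and stood at -0.076 (adjusted p = 0.188) with values floored at the 20th percentile, and WWC1 was at 0.16 with the mean of its probe sets, of which 1 was higher and 1 lower. NF-kB and cytokine genes gave 9 of 21 higher and 4 lower (median 0.07, mean -0.03, adjusted p = 0.518). The fallers were the neutrophil chemokines CXCL3 (-1.89 ± 0.059), CXCL1 (-1.23 ± 0.084) and CXCL2 (-1.22 ± 0.12) and, named afterwards, ICAM1 (-0.64 ± 0.054), while the feedback inhibitor TNFAIP3 rose (1.22 ± 0.070). Interferon-stimulated genes gave 9 of 28 higher and 12 lower (median -0.07, adjusted p = 0.382), with PARP9 (-1.73 ± 0.11) and IFIT2 (-1.32 ± 0.045) lower and ISG20 (1.34 ± 0.043) and IRF7 (1.22 ± 0.069) higher. JAK-STAT and cytokine receptor genes gave 10 of 25 higher and 10 lower (median 0.01, adjusted p = 0.958), with JAK1 (1.29 ± 0.052), SOCS1 (1.14 ± 0.12, but 0.51 with values floored at the 20th percentile), PIM1 (1.14 ± 0.042) and OSMR (1.499 ± 0.049, though 2 of its 4 probe sets were lower and their mean was called lower at -0.14) higher. The NF-kB test pointed up against a negative mean, and the JAK-STAT test down against a mean of 0.07. Counts for these 5 lists were the same adjusted over the list alone, and the YAP/TAZ, TGF-beta, NF-kB and JAK-STAT medians turned negative when scaled to the hybridization controls. The counts higher and lower were then 7 and 9 for YAP/TAZ, 5 and 7 for TGF-beta, 4 and 9 for NF-kB, 6 and 13 for JAK-STAT and 6 and 17 for interferon-stimulated genes.

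Stomach epithelium markers were higher, with 7 of 12 risen, 0 fallen and 5 not passing (median 0.26, adjusted p = 0.0138; adjusted p = 0.403 with an estimated correlation). CA2, the calpain CAPN8 (1.77 ± 0.053), the trefoil peptide TFF1 (1.77 ± 0.10) and cathepsin E, CTSE (0.78 ± 0.038), rose most, and the call was lost when dim genes were left out (adjusted p = 0.153). Scaled to the hybridization controls, 4 rose and 1 fell (median 0.050). The list was called there too (adjusted p = 0.00145), which adds no separate support because all genes shifted alike. Intestinal markers gave 7 of 15 higher and 2 lower (median 0.21, adjusted p = 0.116). REG4 (1.58 ± 0.041), CEACAM6 (1.44 ± 0.043) and CEACAM5 (0.92 ± 0.059) rose, and the microvillus protein VIL1 (-1.03 ± 0.061) and the intestinal transcription factor CDX2 (-0.77 ± 0.046, named after its values were seen) fell. Mesenchymal and migration genes gave 11 of 22 higher, 4 lower and 7 not passing (median 0.24, adjusted p = 0.026; adjusted p = 0.264 with an estimated correlation). MMP1, the urokinase receptor PLAUR (1.31 ± 0.043) and the integrin ITGA5 (0.97 ± 0.079) rose. MMP7 (-0.84 ± 0.22) fell, as did vimentin VIM (-0.44 ± 0.076), S100A4 (-0.32 ± 0.050) and the mesenchymal transcription factor ZEB1 (-0.22 ± 0.058), these last 3 named after their values were seen. MMP7 was not called without control replicate 1 (adjusted p = 0.0584) or 3 (0.0587), nor ZEB1 without knockdown replicate 3 (0.0606). Both were dim, and with values floored at the 20th percentile MMP7 stood at -0.075 (adjusted p = 0.284) and ZEB1 at 0.041. ZEB1 also missed the threshold with the mean of its probe sets (adjusted p = 0.0954) and with a trended robust prior (0.0819). Scaled to the hybridization controls, 6 mesenchymal genes rose and 4 fell (median 0.024). The list was called there too (adjusted p = 0.00414), again without adding separate support. Epithelial junction genes gave 12 of 28 higher and 8 lower (median 0.05, adjusted p = 0.336), with GRHL2, CLDN1 (1.41 ± 0.073) and E-cadherin CDH1 (0.96 ± 0.054) higher and MARVELD2 (-1.01 ± 0.077) lower. Counts for these 4 lists were the same adjusted over the list alone, and the intestinal and epithelial medians turned negative when scaled to the hybridization controls. The intestinal list was called higher under that scaling (adjusted p = 0.0181), although its fold changes relative to the other genes were unchanged. The counts higher and lower were then 6 and 5 for intestinal and 8 and 15 for epithelial genes.

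Markers of other cell types and of handling were not called as lists. Of 8 fibroblast markers 2 rose and 2 fell (median 0.11, adjusted p = 0.834), COL5A1 (0.36 ± 0.10) and COL1A2 (0.28 ± 0.093) being higher and ACTA2 (-0.47 ± 0.060) and PDGFRA (-0.26 ± 0.068) lower, although 2 of the 3 probe sets of PDGFRA were higher and their mean was called higher at 1.15. Of 11 leukocyte markers 4 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.15, adjusted p = 0.178), namely CD68 (0.54 ± 0.065), ITGAM (0.26 ± 0.068), LYZ (0.21 ± 0.067) and CSF1R (0.18 ± 0.055). Of 9 endothelial markers 3 rose and 0 fell (1 and 0 adjusted over the list alone; median 0.18, adjusted p = 0.162), namely ESAM (1.48 ± 0.14; 0.83 with the mean of its probe sets), ROBO4 (0.24 ± 0.075) and TEK (0.21 ± 0.074). Several of these calls were lost when 1 array was left out. COL1A2 was lost without replicate 1 of either group, control replicate 3 or knockdown replicate 2 (adjusted p 0.0886 to 0.117), and COL5A1 without control replicate 1 or 3 or knockdown replicate 2 or 3 (0.0541 to 0.069). ITGAM was lost without control replicate 3 (0.0523) and ROBO4 without replicate 2 or 3 of either group (0.0563 to 0.0974). Leaving out any single array ended the LYZ call, except control replicate 3 (0.0561 to 0.112), the CSF1R call, except control replicate 1 (0.06 to 0.0766), and the TEK call, except control replicate 2 (0.0674 to 0.135). A replicate block gave adjusted p-values of 0.0616 for LYZ and 0.0785 for TEK. With values floored at the 20th percentile, COL1A2, ITGAM and TEK all stood at 0.041 and ROBO4 at 0.14, none of them called, and with the mean of their probe sets CSF1R (0.08) and ROBO4 (0.15) were not called. LYZ, CSF1R and TEK and the medians of all 3 lists turned negative when scaled to the hybridization controls, where COL1A2, COL5A1, ITGAM and ROBO4 were not called and the counts higher and lower were 0 and 2 for fibroblast, 1 and 2 for leukocyte and 1 and 0 for endothelial markers. Immediate early and heat shock genes gave 6 of 18 higher and 6 lower (median 0.04, adjusted p = 0.958), with DUSP1 (1.00 ± 0.064) and JUNB (0.61 ± 0.052) higher and HSPA8 (-0.93 ± 0.043) and EGR1 lower, while 4 of the 9 probe sets of HSPA8 were higher and their mean stood at -0.15. The test of that list pointed down against a mean of 0.01, and its median turned negative under the same scaling (4 higher, 10 lower), as did that of the glycolysis and condensin I lists. Counts for the fibroblast and handling lists were the same adjusted over the list alone. The 3′ minus 5′ signal of the ACTB control transcript was 0.29 ± 0.044 (SD) on control arrays and 0.35 ± 0.019 on knockdown arrays, and that of GAPDH was -0.11 ± 0.028 and -0.084 ± 0.0066.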

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

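The tests of RNA degradation, of the number of calls after rescaling, of the at least 2-fold calls and of the background were chosen only after the result was seen, as was the scaling to the hybridization controls. Several classes of control probe sets read higher on all 3 knockdown arrays than on any control array. The hybridization controls were higher by 0.212 log2 units (18 of 18 probe sets), the poly-A controls, bacterial transcripts added to the RNA before labelling, by 0.211 (24 of 24), the background probes by 0.149 (10 of 10) and the 28S rRNA probe sets by 0.058 (2 of 3). The 18S rRNA probe sets ran the other way, from 12.80 to 12.07, a difference of -0.73. So did the GAPDH (-0.143) and ACTB (-0.071) control probe sets, with 0 of 3 higher in each. Signal outside the tested genes was also found in probe sets with no gene name here, of which 940 passed the threshold (420 higher, 520 lower) and 113 changed at least 2-fold.

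The first pattern is that 53.3% of the tested genes passed the threshold. Of the 10 ways to split the 6 arrays into 3 and 3, 1 gave as many genes, the real one with 8167, and the highest of the others gave 0, but 10 splits are too few for a share under 0.05. The 3′ minus 5′ signal of ACTB and GAPDH differed by at most 0.0588, which argues against a large difference in degradation of these 2 transcripts. Both were bright, with group means of 12.66 to 12.82, where a difference may be compressed. The 18S rRNA probe sets also differed, by -0.73, so a difference in RNA quality stays open. The number of calls was 8141 to 8888 under 4 rescalings, which cannot decide whether array scaling was its whole cause. RMA had already made the arrays alike, so aligning them again could change little. The shift of 0.212 to the hybridization controls exceeds the median standard error of 0.062 and can push unchanged genes past the threshold. Scaling stays open for which genes passed, as 74.9% of the calls held when scaled to the hybridization controls and 93.5% under cyclic loess, and although 100% of the 746 genes changed at least 2-fold passed the adjusted threshold there with the same sign, a uniform shift of 0.212 is too small to undo that, so it decides nothing. A candidate biological explanation is the knockdown itself. With the number of hairpin sequences not given, loss of NCAPD3 cannot be told apart here from other effects of the hairpin lentivirus. Differences between the cell populations that arose during selection or culture also remain untested.

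The second pattern is that the dimmest quartile of genes rose slightly, with 612 called higher and 221 lower (73.5% higher). Their median log2 fold change was 0.0961, the background probes rose by 0.149, and the brightest quartile had a median of -0.034. These values lay within the bounds set for higher background on the knockdown arrays, which may account for small rises of dim genes. The bounds were set after the result was seen, so meeting them is no separate support. The rise was not particular to the dimmest genes or to background, however. The second quartile had a median of 0.0738, and the bright hybridization controls (mean 10.12 on control arrays) rose by 0.212. A biological rise of dim genes was not tested. The 2-fold calls among dim genes went the other way, with 12 higher and 31 lower.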

How the results depend on the processing

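Scaling to the hybridization controls was the only alternative here chosen after the result was seen. NCAPD3 stayed lower and past the threshold under all alternatives that tested it, from -0.89 (hybridization controls) to -0.62 (cyclic loess), and from -0.71 to -0.64 with 1 array left out. Of 228 results, 201 to 225 kept direction and side of the threshold in each alternative that refitted genes and lists, and 197 did with dim genes left out, where fewer genes were tested. Leaving out 1 array gave 7233 to 8812 called genes, 726 to 781 at least 2-fold and 9 to 11 called lists. Dim signal limits fold changes near background, and scanner files, from which background could be corrected again, were not used here. No array slide or scan date was known, so no such block was run.

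With the replicate block, which treats same-numbered arrays as pairs although the correlations leave that uncertain, 8661 genes and 746 at least 2-fold were called. It ended the call of the apoptosis list (adjusted p = 0.0684) and of LYZ, STARD4, TEK and TIGAR, and changed no other call among the 228 results.

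Counts moved by over 1.5 times in these cases. Scaling to the hybridization controls gave 1802 genes higher and 7086 lower, with 189 and 804 at least 2-fold, because the controls' rise was taken off every gene. Testing every probe set gave 21322 calls (10354 higher, 10968 lower), with 2093 at least 2-fold (957 and 1136), as more features were tested. Requiring a change beyond 1.2-fold gave 3789 (1529 higher, 2260 lower). Camera with an estimated correlation called 0 lists, against 11, and fry, which does not compare a list with other genes, called 28. The loss under camera does not rest on higher correlation alone. For the apoptosis and mesenchymal lists the estimates (-0.0086 and -0.023) lay below the preset 0.01. Their unadjusted camera p nevertheless rose, from 0.015 to 0.056 and from 0.0071 to 0.041, so a higher correlation cannot account for the rise in these lists. The other called lists had estimates above the preset.

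With an estimated correlation the adjusted p was 0.264 for the apoptosis, ATF4, endoplasmic reticulum, cholesterol, oxidative phosphorylation, MYC and mesenchymal lists, 0.403 for the p53, ERK and stomach lists and 0.446 for DNA repair. The repair list also missed the threshold after quantile normalization (0.0706), cyclic loess (0.0759), the mean of probe sets (0.0915), scaling to the hybridization controls (0.225) and without dim genes (0.249), and ranged from 0.0317 to 0.0729 with 1 array left out. The apoptosis list missed it with array weights (0.0521) and the mean of probe sets (0.0602), and ranged from 0.0440 to 0.0637 with 1 array left out. The p53 list missed it with the mean of probe sets (0.0851) and the stomach list without dim genes (0.153). Calls were also gained: the ribosomal protein and autophagy lists passed with a trended robust prior (0.0363 and 0.029) and, with the intestinal list, when scaled to the hybridization controls (0.0015, 0.0173 and 0.0181). With an estimated correlation and values as deposited, the ribosomal protein, autophagy and intestinal lists stood at 0.370, 0.592 and 0.370. Scaling to the hybridization controls left the fold changes relative to other genes unchanged. Calls gained or lost there therefore reflect changed test statistics, not changed relative levels. The cause of the other gained and lost calls was not tested.

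Of all 8167 called genes, 7188 (88.0%) kept their call with the mean of all probe sets, and 124 were called in the opposite direction. Scaling to the hybridization controls gave 1 opposite call. Among the named genes, single genes changed sign in 3 settings, as follows. With the mean of all probe sets, which mixes probe sets that disagree, values were 0.21 for NCAPG2, 0.032 for NCAPH2, -0.14 for OSMR, 1.15 for PDGFRA, -0.14 for SREBF2, 0.033 for AXIN2, 0.16 for WWC1 and -0.74 for KIAA0040. Other genes kept their sign but moved less, among them CDKN2B (0.39), EGR1 (-0.31), VIL1 (-0.57), ESCO2 (-0.63), CXCL1 (-0.71) and WDR12 (-0.71). Some moved more, such as MKI67 (-1.61) and TIGAR (-1.25). Scaled to the hybridization controls, they were -0.18 for NCAPD2, -0.17 for NCAPH, -0.16 for SMC2, -0.0068 for LYZ, -0.032 for CSF1R, -0.0026 for TEK, -0.037 for SREBF2, -0.014 for STARD4, -0.024 for CDCA5 and -0.038 for SMC3. The floor left ZEB1 at 0.041, the shift of the floored values. Fry called the JAK-STAT list upward (adjusted p = 0.0421), against camera's downward sign. Medians of lists turned as well, from positive to negative for 13 lists under the scaling to the hybridization controls, to 0.032 for condensin II with the mean of probe sets and to 0.0007 for DNA replication under cyclic loess.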

Other observations

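The tests of splicing and cleavage factors, opposite probe sets, gene order and gene span were set after the data had been opened but before their own results were seen. The genes named below were chosen after their values were seen, and the factor list was written once SRSF3, PCF11 and PPP1R10, which it leaves out, had been seen to fall. Many of the listed RNA processing factors were lower in the knockdown. SRSF3, a serine- and arginine-rich splicing factor, fell by 1.89 ± 0.057, with all 6 of its probe sets lower, and PCF11, a factor that ends transcripts, fell by 2.24 ± 0.12 (-1.34 with values floored at the 20th percentile). Of 31 other factors of these classes 20 fell, 5 rose and 6 did not pass, with a median of -0.319 (camera p = 0.00014; p = 0.228 with an estimated correlation). Among them were CSTF3 (-1.60 ± 0.049), SRSF8 (-1.48 ± 0.091), RBBP6 (-1.33 ± 0.053), SRSF2 (-0.85 ± 0.043) and SRSF1 (-0.84 ± 0.039), although the probe sets of CSTF3 and RBBP6 disagreed.

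Probe sets of the same gene moved apart in 775 of 9263 genes with several (8.37%), and in 17 genes both directions reached 2-fold. In KLF3, a transcriptional repressor, probe set 11759749_at rose by 3.76 ± 0.054 and 11729232_s_at fell by 2.13 ± 0.061, while in MDM4, a p53 inhibitor, 11721914_a_at rose by 1.502 ± 0.051 and 11721913_x_at fell by 1.00 ± 0.068. MYO10 (1.86 ± 0.064 and -1.496 ± 0.13) and KIAA0040 (1.41 ± 0.052 and -1.89 ± 0.059) were similar. Noise of dim probe sets as the whole cause is argued against, since 6.20% of genes whose probe sets all lay above the median intensity (175 of 2821) had calls both ways, against 9.31% of the rest. As a hypothesis, transcript ends or splicing may differ between the populations, in line with the median of -0.319 for the factors above, but probes that match other transcripts were not tested and no isoform was measured.

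Copy number differences of whole chromosomes between the populations are argued against as the source of the calls, because all chromosome medians lay between 0.015 and 0.075. Log2 fold changes of 15251 neighbouring gene pairs correlated weakly, at r = 0.0646, but above the highest of 1000 shuffled orders (0.0301). Copy number differences over smaller stretches therefore stay open. Genomic span had a Spearman correlation with log2 fold change of -0.014 over genes, and of -0.077 to 0.081 within quartiles of intensity. Genes are not independent replicates.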
